A study of Mus musculus with 12 samples.

How the data were processed

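Gene expression was measured on Affymetrix mouse whole-genome arrays in dendritic cells (DCs) sorted from spleens of alymphoplasia (aly) mice, which carry a mutation of Map3k14 (the kinase NIK), and of heterozygous littermates, called wild type (WT) here. Mice were left untreated or received LPS (25 micrograms) together with an agonistic antibody against CD40 (100 micrograms), and DCs were taken 6 hours later. Each of the 4 groups (WT untreated, aly untreated, WT treated, aly treated) had 3 arrays, and each array held RNA of DCs pooled from 3 mice, enriched on CD11c beads and then sorted by flow cytometry. The p-values below therefore measure the spread between arrays of pooled DCs and not between single mice. RNA went through 2 rounds of amplification before labelling.

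The deposited values are of the unit intensity, 1 value for each of 45101 probe sets on each of 12 arrays, on a linear scale. The 2% trimmed mean was 150.001 on every array, as a scaling of each array to a common target gives. The scaling of the arrays can thus be read from the values, whereas the software and its background step are not given in the sources used here, so the background step stays unknown. Column medians were 21.9, 22 and 25.1 (WT untreated replicates 1 to 3), 26.6, 26.6 and 39.1 (aly untreated), 21.5, 23.9 and 21.6 (WT treated), and 53.4, 23.3 and 26.7 (aly treated). Calls of presence were not used here, so no gene is described as silent, and the offset understates the fold changes of genes with low values. All columns of the table were matched to samples (0 unmatched).

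Of the probe sets, 34958 carried 1 gene symbol, 932 several symbols, 9211 none, and 64 were controls. Only probe sets with 1 symbol were named, and 34754 of them were matched to the gene table by their Entrez identifier, which changed 0 symbols. Probe sets above the 40th percentile of their array on at least 3 arrays were kept (34205 past this filter, controls left out), and each gene was represented by its probe set with the highest mean, which left 15019 genes. Several filtered probe sets were present for 6965 genes.

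Values were log2 transformed after adding 16 and used as deposited, without further normalization. Linear models were fitted in limma 3.58.1 (R 4.3.3, with version 1.17.8 of the package data.table) to all 12 arrays with 1 mean per group and moderated variances (8 residual degrees of freedom, prior degrees of freedom 8.04). The 5 contrasts were treated minus untreated in WT, treated minus untreated in aly, aly minus WT among untreated, aly minus WT among treated, and the genotype by treatment interaction (response of aly minus response of WT). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. The median standard error was 0.43 log2 units in the first 4 contrasts and 0.61 in the interaction. All p-values of genes are adjusted limma p-values unless stated, log2 changes are given with the standard error of the fit (n = 3 arrays per group), and linear levels are means with standard deviations. Fold changes were computed from the log2 changes.

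Gene lists were fixed before the data were examined, and so were the filter, the offset, the tests, the named-gene rule and a first set of alternatives. The 33 lists hold 594 entries, of which 518 were measured (6 through a synonym), or 558 distinct symbols with 486 measured. They cover the NF-kB pathway, DC maturation, cytokines, chemokines, chemokine receptors, non-canonical NF-kB chemokine targets, interferon-stimulated genes, MHC class I presentation, MHC class II presentation, phagosome and cross-presentation, antigen uptake receptors, Toll-like receptor signalling, negative feedback of cytokine signalling, apoptosis and survival, cell cycle, glycolysis, oxidative phosphorylation, cholesterol synthesis, and immediate early and heat shock genes. Marker lists cover CD8 alpha positive DCs (cDC1), CD4 or CD11b positive DCs (cDC2), pan-DC genes, plasmacytoid DCs, B cells, plasma cells, T cells, natural killer cells, neutrophils, monocytes, red pulp macrophages, marginal zone macrophages, erythroid cells, and stromal and endothelial cells. Each list was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera with a correlation estimated from the arrays and fry, whose p asks whether the genes of a list move one way, stand beside it. Members were also counted over all genes and adjusted over the list alone.

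Genes were named by a rule. For each contrast it took the 10 largest rises and 10 largest falls among called genes with an absolute log2 change of at least 1 and no overlap between the arrays of the groups compared (no overlap rule in the interaction), and up to 4 members with the smallest p of each list described. Map3k14, Nfkb2, Relb, Cd40, Cd80, Cd86, Il12b and Ccr7 were always named, and the largest changes of the WT treatment were also read in the interaction. A gene outside the rule is named only where stated.

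Array quality was read from the control probe sets, as the 3' over 5' ratios of Actb and Gapdh, the hybridisation controls and the poly-A spike-ins, and from correlations between arrays and principal components. Treated aly replicate 1 was of low quality and was kept in the main analysis, with each count also given without it. Replicate 1 of every group lacked the poly-A spike-in signal that replicates 2 and 3 had, so this division of the arrays, called the spike-in batch although the labels do not state a batch, was added as a block and results were also computed from replicates 2 and 3 only and from replicate 1 only.

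Alternatives chosen beforehand were offsets of 1 and 64, quantile normalization, median centring of each array, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, all probe sets tested singly, the replicate number as a block, a fit of only the groups compared, array weights, variances with trend and robust moderation, a minimum log2 change of 1, each array left out in turn, and for lists the estimated correlation and fry. The spike-in batch, the removal of the 2 arrays with the highest Actb ratio, and the 3' over 5' ratio as a covariate were added after the data were seen. Where a named call rested on 1 of several probe sets of a gene, log2 values of the others are printed beside a stated size if any read far smaller or in the opposite direction. Other groupings of the arrays were tested as all 10 splits of 6 arrays into groups of 3 and, for the interaction, as 100 draws of genotypes within treatments. Intervals are at 95%, with 10000 bootstrap draws where stated.

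The workflow was tested on simulated data with the spread of the real arrays, in which known log2 changes of 1, 2 and 3 were added to 67, 67 and 66 genes. Calls reached 1.5%, 50.7% and 95.5% of them in the contrast built as WT treatment, with 1 unchanged gene called, and 4.5%, 61.2% and 95.5% in the contrast built as aly treatment, with 2 unchanged genes called. Of 30 unshifted lists, 0 were called in either. The genes were simulated as independent, so this does not show how often lists of correlated genes are called falsely. With all arrays alike the shares were 22.4%, 94% and 100% in the first contrast, with 15 unchanged genes called, and 13.4%, 89.6% and 100% in the other, with 7. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.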

Results

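Splenic DCs of WT and aly mice were compared before and 6 hours after LPS with an agonistic antibody against CD40, to find which transcripts of DC activation depend on intact NIK. The treatment raised interferon-stimulated and maturation genes strongly in WT DCs and less in aly DCs. Genes of red pulp macrophages and erythroid cells read higher in aly samples, treated or not, although with an estimated correlation these lists did not pass (adjusted p = 0.12 for both untreated, and 0.23 and 0.16 treated).

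The arrays differed in RNA quality by genotype. The mean log2 3' over 5' ratio of the Actb and Gapdh controls was 3.07 ± 1.31 on aly arrays and 1.57 ± 0.18 on WT arrays (mean ± SD, n = 6 each, exact permutation p = 0.00216), and 2.56 on aly arrays without treated aly replicate 1. On that array the Actb ratio was 55.82, against 1.386 to 1.937 on WT arrays and 1.781 to 5.921 on the other aly arrays. Its hybridisation controls averaged 15660 (1077 to 2183 elsewhere), and its rank correlation with the other arrays was 0.577 to 0.665. The poly-A spike-ins read 4.667 to 16.26 on replicate 1 of each group and 87.75 to 690 on replicates 2 and 3. This points to a technical batch balanced across the groups, which the labels do not state. With scaling to a common trimmed mean, the log2 changes over all genes were not centred. Their median was -0.116 for treatment in WT, -0.076 for treatment in aly and 0.104 for genotype in untreated DCs. It was 0.188 for genotype in treated DCs (0.119 without treated aly replicate 1) and 0.042 for the interaction.

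**Figure D1:**
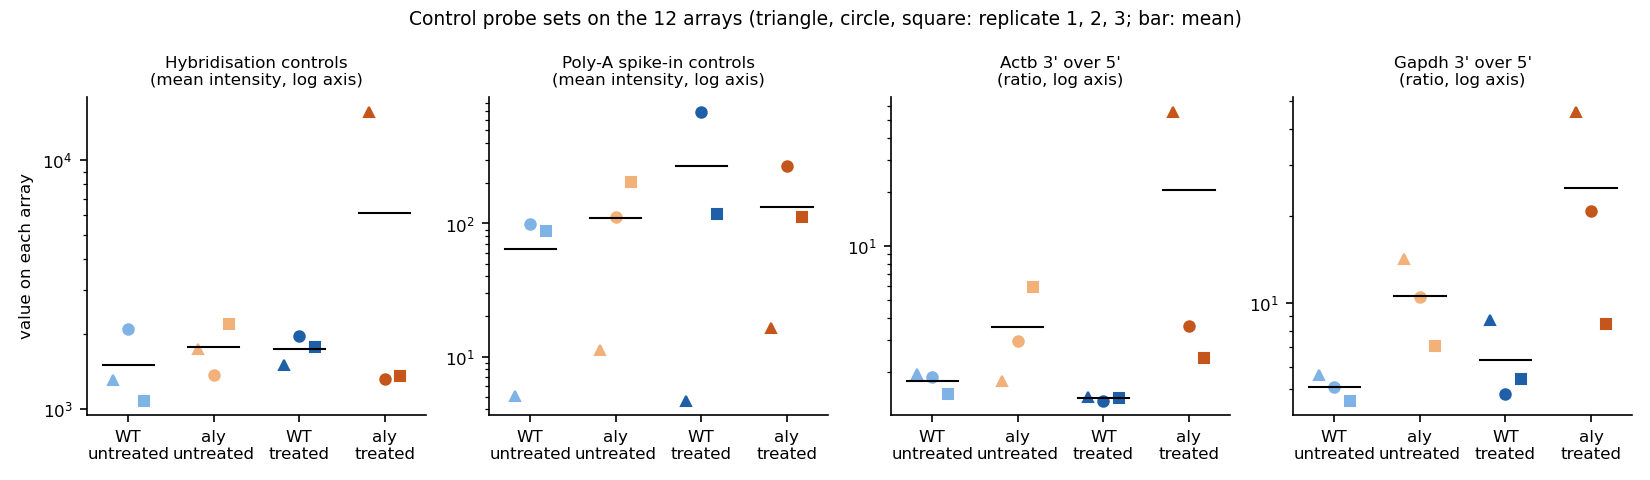
Array quality for the 12 arrays by group, with 1 point per array (triangle, circle and square for replicates 1, 2 and 3). Treated aly replicate 1 stands apart with an Actb 3' over 5' ratio of 55.82 and hybridisation controls of 15660, and the poly-A spike-ins of replicate 1 lie between 4.667 and 16.26 in every group.

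Map3k14, the gene mutated in aly mice, had similar levels in untreated DCs of both genotypes (157 ± 44.6 in WT and 167 ± 53.2 in aly, mean ± SD, n = 3 each). The log2 difference was 0.08 ± 0.50 (adjusted p = 0.97). A probe set reads the amount of transcript and not a point mutation, so this level checks nothing about the genotype labels. With treatment Map3k14 rose in WT to 519 ± 50.1 (log2 change 1.66 ± 0.50, 3.16-fold, adjusted p = 0.048). The change in aly, to 296 ± 234, was not called (0.48 ± 0.50, adjusted p = 0.7, and 1.15 without treated aly replicate 1). The WT call was lost on leaving out any single array other than treated aly replicates 1 and 3, with adjusted p between 0.003 and 0.17 over all 12 omissions. Map3k14 was not called different between the treated genotypes (-1.11 ± 0.50, 95% interval -2.17 to -0.04, adjusted p = 0.2) or in its response (-1.18 ± 0.71, -2.69 to 0.33, adjusted p = 0.71). Without treated aly replicate 1 these differences were -0.44 and -0.51.

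In WT DCs the treatment raised Ramp3, the calcitonin receptor partner, by 6.70 ± 0.56 log2 units (104-fold, adjusted p = 2.5e-06, n = 3 per group). The cytokine gene Ifng (6.51 ± 0.79, 91.4-fold), the interferon-induced Oasl1 (6.19 ± 0.56, 73.2-fold) and the lipid kinase gene Sphk1 (6.10 ± 0.45, 68.7-fold, other probe set 2.10) rose as well. The interleukin 1 antagonist Il1rn rose 68.3-fold (6.09 ± 0.42, other probe sets 2.95 and 4.88) and Il2ra, the high-affinity interleukin 2 receptor chain, 61.8-fold (5.95 ± 0.39). Untreated WT levels of Ramp3, Ifng, Sphk1 and Il2ra averaged 6.53, 7.73, 10.6 and 3.67, under the added 16, which therefore sets the size and order of their folds. With an offset of 1 all 4 estimates were larger and Il2ra came before Ifng and Sphk1. The folds of Il6, Ikbke, Fas, Socs1 and Adgrl3 below depend on the 16 likewise. The lymph node homing receptor Ccr7 rose 26.6-fold (4.74 ± 0.38, adjusted p = 2e-06). The costimulatory genes Cd80 and Cd40 rose 15.6-fold (3.96 ± 0.39, adjusted p = 9.4e-06, other probe sets 2.46, 2.55 and 0.63) and 11.9-fold (3.58 ± 0.50, adjusted p = 0.00026). Nfkb2, which encodes the substrate of the NIK pathway, rose 10.4-fold (3.39 ± 0.48, adjusted p = 0.00029) and its partner Relb 6.15-fold (2.62 ± 0.44, adjusted p = 0.0012). Cd86 rose 3.32-fold (1.73 ± 0.39, adjusted p = 0.01), a call lost without WT untreated replicate 1 or 2 or WT treated replicate 3 (adjusted p up to 0.071). Il12b, which encodes the p40 chain of interleukin 12, was not called (0.15 ± 0.40, adjusted p = 0.89).

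Among the falls in WT were the receptor Gpr34 (-4.05 ± 0.53, 16.6-fold, adjusted p = 0.00013) and Xcr1, the chemokine receptor of cDC1 (-3.98 ± 0.75, 15.8-fold, adjusted p = 0.0028). The adhesion receptor Adgrl3 fell 13-fold (-3.70 ± 0.35, adjusted p = 6.9e-06, 5 other probe sets at -2.34 to -0.78) and the small GTPase gene Rab7b 19.2-fold (-4.27 ± 0.85, adjusted p = 0.0044, others -3.05 and -1.27). In all, 1458 of 15019 genes were called in WT, 744 higher and 714 lower, and 2843 without treated aly replicate 1 (1172 and 1671).

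Interferon-stimulated genes were the most strongly raised list in WT. Of 32 measured, 28 rose over all genes (31 adjusted over the list alone), with a median of 3.39. Camera gave adjusted p = 8.5e-43, and adjusted p = 0.006 with an estimated correlation. They included Gbp2, a GTPase of cell-autonomous immunity (5.69 ± 0.39, 51.5-fold), the RNA-binding Ifit1 (4.94 ± 0.50, 30.8-fold) and the regulator Irf7 (4.31 ± 0.40, 19.8-fold). The median was 3.32 in replicates 2 and 3 and 3.48 in replicate 1. Of 22 maturation genes 18 rose (19 adjusted over the list alone). Their median was 2.71 (2.67 in replicates 2 and 3, 2.68 in replicate 1, adjusted p = 2.3e-22, and 0.001 with an estimated correlation). Among them were Cd200, an inhibitory ligand (4.08 ± 0.44, 16.9-fold), and Stat4, which relays interleukin 12 signals (3.72 ± 0.40, 13.2-fold).

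Negative feedback genes rose as well, 13 of 17 over all genes and 14 adjusted over the list alone. Their median was 2.54 (adjusted p = 1.1e-18, and 0.0023 with an estimated correlation). The inhibitors of cytokine signalling Socs2 (21.9-fold, 5 other probe sets at log2 changes of -0.05 to 4.97), Socs3 (19.7-fold) and Socs1 (6.7-fold) were among them. In the NF-kB pathway 11 of 21 rose (15 adjusted over the list alone), with the kinase Ikbke (14.8-fold), the ubiquitin ligase Birc2 (8.03-fold) and the inhibitor Tnfaip3 (4.52-fold). The median of the pathway was 1.69 (1.57 in replicates 2 and 3, 1.76 in replicate 1, adjusted p = 6.8e-14, and 0.01 with an estimated correlation). Of 19 chemokines 8 rose and 1 fell (9 and 1 adjusted over the list alone). The T cell attractants Cxcl10 (53.5-fold), Ccl22 (51.2-fold), Cxcl11 (39.1-fold, but a log2 change of only 1.04 on its other probe set) and Ccl5 (9.47-fold) led them. The median of the chemokines was 1.32 (adjusted p = 1e-09, and 0.042 with an estimated correlation).

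MHC class I genes rose in 5 of 15 cases (7 adjusted over the list alone), among them the transactivator Nlrc5 (7.87-fold) and the peptide editor Tapbp (3.66-fold). Their median was 0.79 (adjusted p = 1.3e-05, and 0.014 with an estimated correlation). Of 18 apoptosis and survival genes 6 rose (7 up and 1 down adjusted over the list alone, median 0.66, adjusted p = 0.00026, and 0.015 with an estimated correlation). The risen members act on both sides, since Fas (28.7-fold) and Casp4 (10.7-fold) promote cell death and Bcl2l1 (8.78-fold, other probe set at a log2 change of 1.09) opposes it. Of 18 cytokines 4 rose and 1 fell (5 and 1 adjusted over the list alone), with Il6 (11.7-fold) and Il15 (9.69-fold) rising. Their median was 0.50 (adjusted p = 0.0015, and 0.11 with an estimated correlation). Among 7 non-canonical NF-kB chemokine targets 2 rose (2 adjusted over the list alone, median 0.60, adjusted p = 0.023, and 0.23 with an estimated correlation). These were Ccl22 and the adhesion gene Icam1 (3.78-fold), the latter not called without WT untreated replicate 3 or WT treated replicate 3 (adjusted p up to 0.062).

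Markers of cDC1 fell in WT, with 10 of 16 lower and 1 higher (11 and 1 adjusted over the list alone). Their median was -2.77 (-2.65 in replicates 2 and 3, -3.02 in replicate 1, adjusted p = 2e-05, and 0.23 with an estimated correlation). Cd8a, the marker that names the subset, fell 7.5-fold (-2.91 ± 0.50, 4 other probe sets at -3.28 to -1.40) and the double-stranded RNA receptor Tlr3 fell 9.85-fold. The uptake receptor Ly75 rose 4.49-fold (2.17 ± 0.43). Cell cycle genes fell too, 8 of 24 over all genes and 11 adjusted over the list alone, with the centromere gene Cenpa lower by 3.1-fold (-1.63, other probe sets -0.13 and 0.24). Their median was -1.23 (-0.94 in replicates 2 and 3, -1.63 in replicate 1, adjusted p = 2e-06, and 0.2 with an estimated correlation).

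The WT count was 710, 927 and 651 without WT untreated replicates 1, 2 and 3, and 640 and 587 without WT treated replicates 1 and 3. It was 898 with an offset of 1, 893 with median centring (68.2% higher, against 51% as deposited), 1752 with the spike-in batch as a block and 1132 in replicates 2 and 3 alone.

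In aly DCs the treatment raised 1700011B04Rik, an uncharacterised gene, by 5.35 ± 0.38 log2 units (40.8-fold, adjusted p = 3.4e-06, n = 3 per group), from an untreated level of 6.27 under the added 16. The actin-binding gene Cnn3 rose 28.2-fold (4.82 ± 0.53, adjusted p = 0.00057, 5 other probe sets at 0.92 to 3.54) and Ccr7 10.8-fold (3.44 ± 0.38, adjusted p = 0.00057). Socs3 rose 10.8-fold (3.43 ± 0.46, adjusted p = 0.0025) and Il1rn 8.84-fold (3.14 ± 0.42, adjusted p = 0.0025, other probe sets 1.33 and 1.53). These 5 genes were called without any 1 of the 12 arrays. Ramp3 rose 12.9-fold (3.69 ± 0.56), Oasl1 12.2-fold (3.61 ± 0.56, and 2.97 without treated aly replicate 1) and Cxcl10 9.24-fold (3.21 ± 0.52, and 2.57 without it). Not called were Cd40 (2.11 ± 0.50, adjusted p = 0.087, and 1.37 without that array), Nfkb2 (1.83 ± 0.48, adjusted p = 0.14), Cd80 (1.00 ± 0.39, adjusted p = 0.33), Relb (0.98 ± 0.44, adjusted p = 0.37), Cd86 (-0.07 ± 0.39, adjusted p = 0.96) and Il12b (-0.16 ± 0.40, adjusted p = 0.89).

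Called genes numbered 73 in aly, 68 higher and 5 lower, and 55 without treated aly replicate 1, all higher, with 49 in common. The 5 falls (Ramp1, Hepacam2, Homer2, Lpcat2 and Nek6) all lost their call without that array, at adjusted p of 0.077, 0.09, 0.081, 0.082 and 0.068. Other probe sets of Homer2 read 1.04, the opposite direction, and -1.46, against -2.49 for the one used, and those of Nek6 read 0.21 and -0.49 against -1.73. Those of Ramp1 read -1.18 and -0.66 against -2.58, and that of Lpcat2 -0.71 against -2.16. All 68 genes that rose in aly also rose in WT (3.37 expected if the calls were independent), and 3 of the 5 falls also fell in WT (0.238 expected). Without treated aly replicate 1, 55 of 55 rises did so (4.29 expected). The contrasts share no arrays, but their calls share 1 spread per gene from all arrays fitted, which by itself favours overlap. The 744 genes that rose in WT had a median of 2.12 there and 0.87 in aly (0.72 without the array), with 659 in the same direction. The 714 genes that fell in WT had medians of -1.74 and -0.78 (-0.46 without the array), with 657 in the same direction. These genes were selected by their change in WT, which by itself favours a larger median there.

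**Figure D2:**
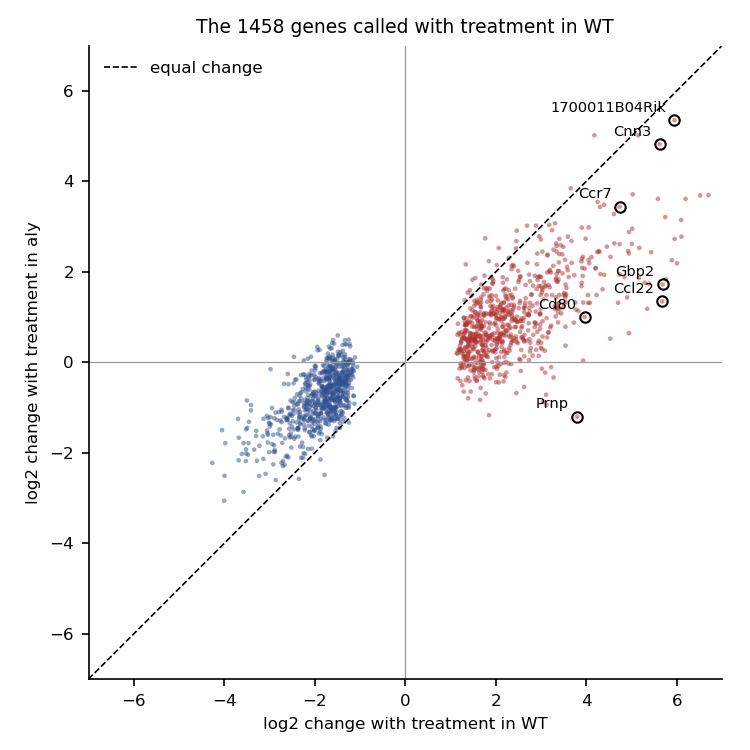
Log2 change on treatment in aly (vertical axis) against that in WT (horizontal axis) for the 1458 genes called in WT, with 1 point per gene (red rose, blue fell, dashed line for equal change). The genes that rose in WT had a median log2 change of 2.12 in WT and 0.87 in aly.

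**Figure D3:**
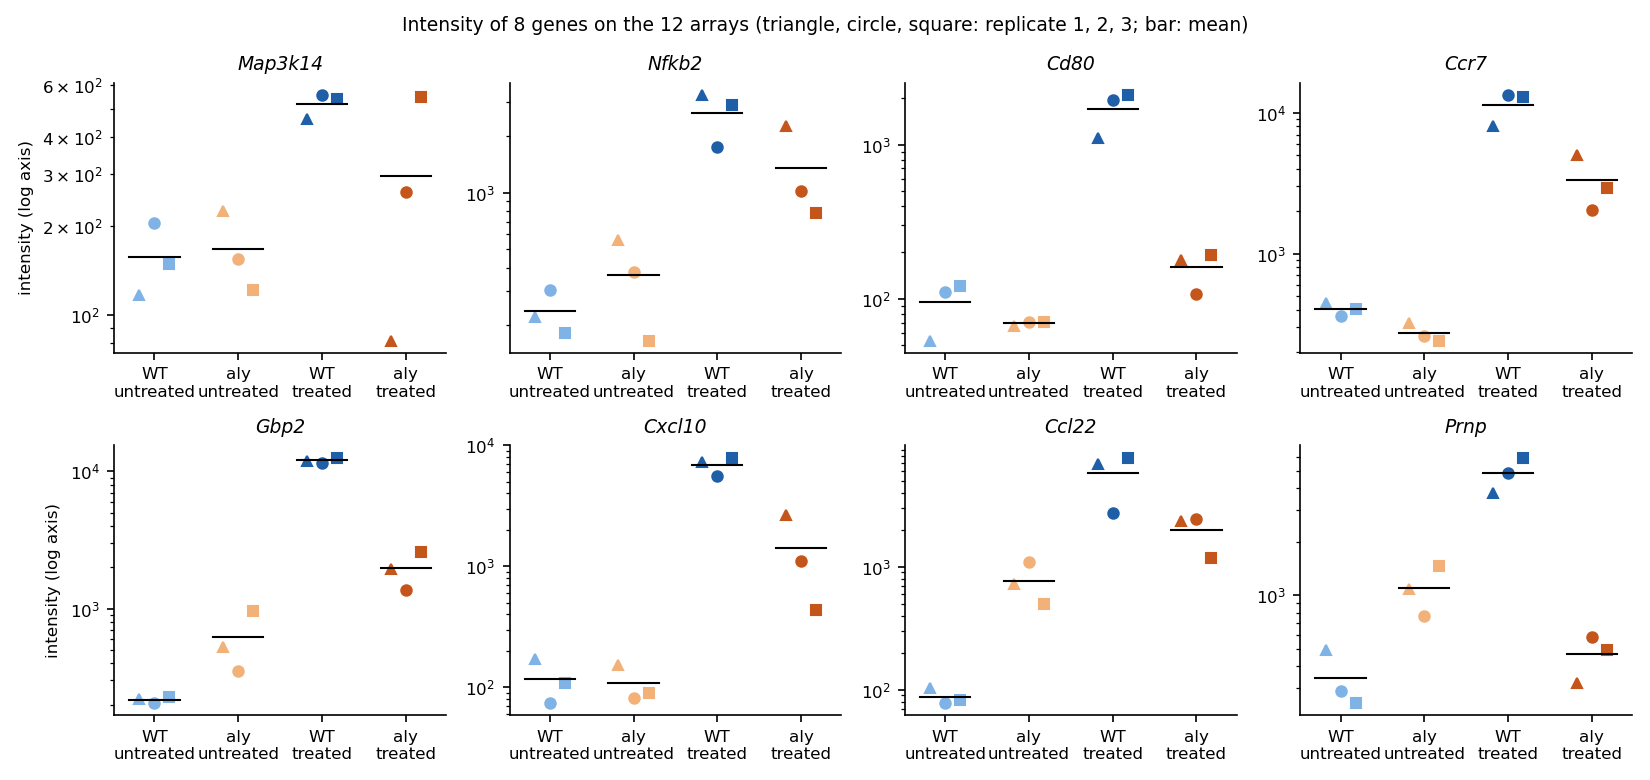
Intensity of 8 genes on each array on a log axis, by group (triangle, circle and square for replicates 1, 2 and 3, bar for the group mean). Cd80 averaged 1710 on treated WT arrays and 160 on treated aly arrays, from 95.3 and 69.7 without treatment.

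Several of the lists raised in WT were raised in aly to a smaller extent. Of 32 interferon-stimulated genes 5 rose over all genes (21 adjusted over the list alone) and 3 without treated aly replicate 1. Their median was 1.48 (1.09 in replicates 2 and 3, 1.88 in replicate 1, adjusted p = 1.1e-23, and 0.037 with an estimated correlation). Ifit1 rose 7.36-fold (2.88 ± 0.50, adjusted p = 0.018). Of 22 maturation genes 2 rose, Ccr7 and the signalling inhibitor Socs2 (8 adjusted over the list alone). For Socs2 the 5 other probe sets read 0.15 to 1.66 against 2.56. Their median was 1.04 (0.95 in replicates 2 and 3, 1.45 in replicate 1, adjusted p = 1.2e-10, and 0.012 with an estimated correlation). Of 17 negative feedback genes 3 rose (6 adjusted over the list alone, median 0.92, adjusted p = 2.5e-11, and 0.012 with an estimated correlation). The NF-kB pathway rose with 1 member called, the adaptor gene Traf1 (5 adjusted over the list alone, median 0.61, adjusted p = 4.7e-07, and 0.064 with an estimated correlation). Chemokines rose with Cxcl10 and Ccl5 called (5 adjusted over the list alone, median 0.91, adjusted p = 8e-06, and 0.17 with an estimated correlation). Apoptosis and survival genes rose with the growth arrest gene Gadd45b (2.39, other probe sets 0.44 and 2.41) and Fas called (6 up and 1 down adjusted over the list alone, median 0.34, adjusted p = 0.0073, and 0.064 with an estimated correlation). Cytokines rose with 1 of 18 called (2 up and 1 down adjusted over the list alone, median 0.27, adjusted p = 0.033, 0.33 with an estimated correlation and 0.17 without treated aly replicate 1). MHC class I genes were not called as a list (0 of 15 by limma, 0 adjusted over the list alone, median -0.02, adjusted p = 0.54), nor were non-canonical NF-kB chemokine targets (0 of 7 by limma, 2 adjusted over the list alone, median 0.12, adjusted p = 0.3) or cholesterol synthesis genes (0 of 16 by limma, 2 adjusted over the list alone, median 0.10, adjusted p = 0.14).

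The aly count was 39 and 42 without WT untreated replicates 1 and 3, 19, 19 and 13 without aly untreated replicates 1 to 3, 48 without WT treated replicate 3, 11 with an offset of 1, 45 with median centring, 120 with the spike-in batch as a block and 28 in replicates 2 and 3 alone. Fitting only the groups compared gave 6, and array weights gave 164. Calls were lost for Traf1 without treated aly replicate 1 (adjusted p = 0.094), for Ramp3 without aly untreated replicate 1 (0.062), for Oasl1 without replicate 3 (0.066), and for Cxcl10, Ccl5 and Ifit1 without replicate 2 or 3 of that group (up to 0.087, 0.099 and 0.099), while Socs2, Gadd45b and Fas were lost without 7, 3 and 12 of the arrays.

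Samples of untreated aly DCs read higher than those of untreated WT DCs for transcripts of tissue macrophages. As a list these did not pass with an estimated correlation, and RNA quality differed by genotype. The complement genes C1qa (4.62 ± 0.80, 24.5-fold, adjusted p = 0.024, n = 3 per group) and C1qc (4.54 ± 0.85, 23.2-fold, adjusted p = 0.027) were higher in aly. So were the mannose receptor Mrc1 (4.17 ± 0.81, 18-fold), the phagocytic receptor Mertk (4.03 ± 0.69, 16.4-fold) and Spic, the transcription factor of red pulp macrophages (3.17 ± 0.54, 8.98-fold). On untreated WT replicates 1 to 3 C1qa read 637.8, 35.2 and 54.6. The erythrocyte anion exchanger Slc4a1 was 25.8-fold higher in aly (4.69 ± 0.71, adjusted p = 0.018, other probe sets 0.48 and 4.36). Slc4a1 is among the 100 measured genes nearest to Map3k14, so differing flanking DNA cannot be told apart for it. Ccl22, a chemokine of mature DCs, was 7.29-fold higher in aly (2.87 ± 0.45, adjusted p = 0.019), at 502 to 1090 against 78.2 to 102 in linear units. The metabolite receptor Sucnr1 (-3.22 ± 0.60, 9.29-fold), the protease inhibitor gene Serpinb2 (-3.03 ± 0.51, 8.15-fold) and Adgrl3 (-2.10 ± 0.35, 4.29-fold, other probe sets -0.51, -1.37, -0.16, 0.52 and -1.01) were lower. Before treatment there was no call for Nfkb2 (0.49 ± 0.48, adjusted p = 0.77), Relb (-0.28 ± 0.44, 0.87), Cd40 (0.59 ± 0.50, 0.73), Cd80 (-0.32 ± 0.39, 0.82), Cd86 (0.14 ± 0.39, 0.94), Ccr7 (-0.54 ± 0.38, 0.67) or Il12b (0.10 ± 0.40, 0.95).

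All 12 red pulp macrophage genes had positive differences and 6 were called over all genes (11 adjusted over the list alone). Without treated aly replicate 1 the number called over all genes was 11. The median was 3.62 (4.80 in replicates 2 and 3, 2.01 in replicate 1, adjusted p = 5.4e-17, and 0.12 with an estimated correlation). All 7 erythroid genes were positive, with 1 called (5 adjusted over the list alone). Their median was 1.28 (1.62 in replicates 2 and 3, 0.79 in replicate 1, adjusted p = 5.2e-06, and 0.12 with an estimated correlation). Of 20 antigen uptake receptors 5 were higher (9 adjusted over the list alone, median 0.69, adjusted p = 0.00017, and 0.41 with an estimated correlation). Among them were the endocytic receptor gene Lrp1 (11.5-fold) and the Fc receptor gene Fcgr1 (7.96-fold, other probe set at a log2 difference of 1.09), which macrophages also express. Pan-DC genes were lower as a list, with only P2ry10 called among 12 (1 adjusted over the list alone, median -0.44, adjusted p = 0.0081, and 0.47 with an estimated correlation). Non-canonical NF-kB chemokine targets were higher with 1 of 7 called, Ccl22 (2 adjusted over the list alone, median 0.84, adjusted p = 0.0018, and 0.31 with an estimated correlation). Monocyte genes were higher with 1 of 8 called (3 adjusted over the list alone, median 1.06, adjusted p = 0.01, and 0.47 with an estimated correlation). Marginal zone macrophage genes were higher with 0 of 6 called by limma (3 adjusted over the list alone, median 1.47, adjusted p = 0.03, and 0.41 with an estimated correlation). Chemokines were higher with 1 of 19 called (1 adjusted over the list alone, median 0.61, adjusted p = 0.03, and 0.47 with an estimated correlation), and cell cycle genes were lower with 0 of 24 called by limma (0 adjusted over the list alone, median -0.32, adjusted p = 0.01, and 0.54 with an estimated correlation). Neutrophil genes (0 by limma, 0 adjusted over the list alone, median 0.92, adjusted p = 0.3) and stromal and endothelial genes (0 by limma, 3 adjusted over the list alone, median 0.81, adjusted p = 0.11) were not called as lists. Interferon-stimulated genes (median 0.01, adjusted p = 0.86) and maturation genes (median 0.10, adjusted p = 0.78) did not differ, and the sign of both medians turned with the scaling.

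The untreated comparison had 83 calls, 75 higher and 8 lower in aly, and 396 without treated aly replicate 1 (288 and 108). The limma count was 1 and 0 without WT untreated replicates 2 and 3, 0, 4 and 0 without aly untreated replicates 1 to 3 (unadjusted counts of 1051, 1258 and 1435 where it was 0), and 45 without WT treated replicate 2, so each gene named here lost its call without some untreated array. It was 0 with an offset of 1 (1505 unadjusted), 0 with median centring (1365 unadjusted), 51 with an offset of 64, 176 with the spike-in batch as a block and 231 in replicates 2 and 3 alone. The replicate number as a block gave 133, and the 3' over 5' covariate without treated aly replicate 1 gave 0 by limma.

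**Figure D4:**
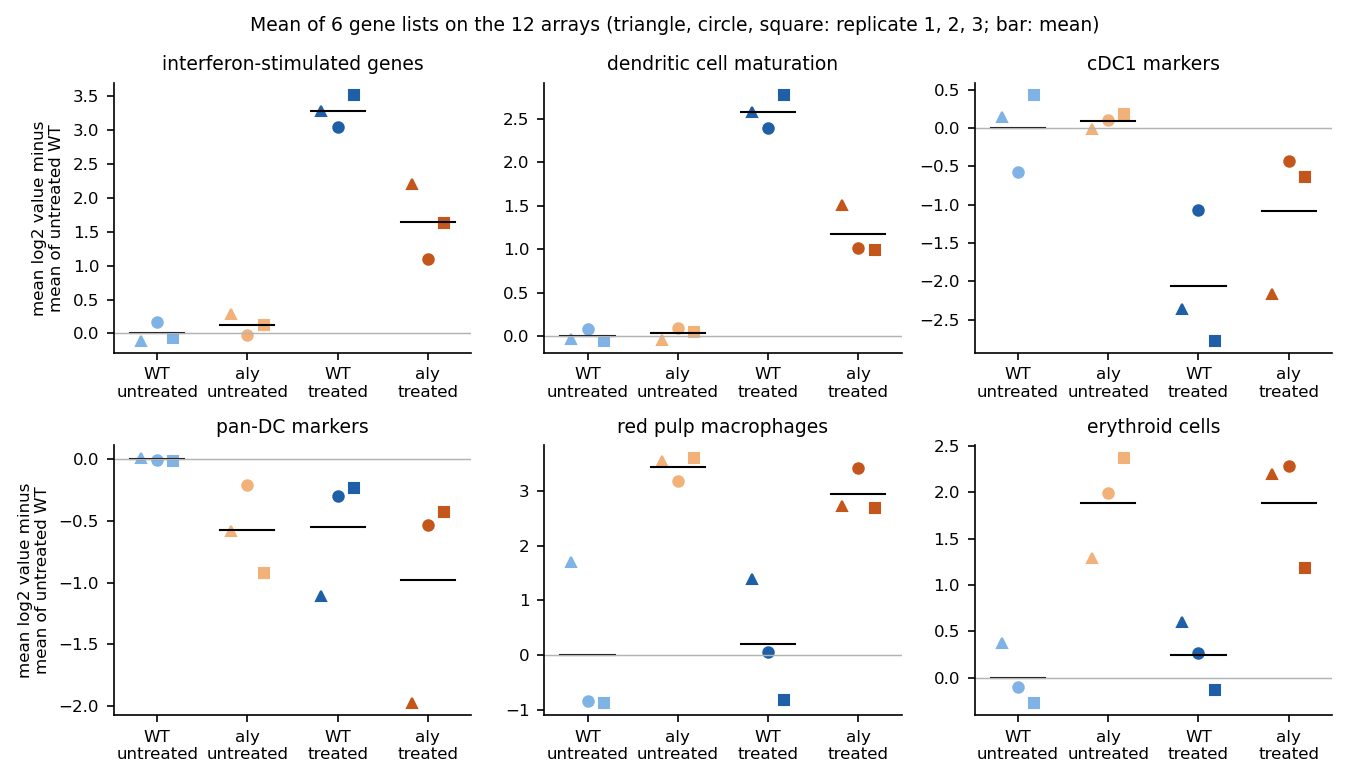
Mean log2 value of 6 lists on each array minus the mean of untreated WT, by group (triangle, circle and square for replicates 1, 2 and 3, bar for the group mean). Red pulp macrophage genes lay at 3.191 to 3.616 on untreated aly arrays and at -0.872 to 1.707 on untreated WT arrays.

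After treatment aly DCs had less of many activation transcripts than WT DCs. Vsig10, an immunoglobulin family gene, was 21.3-fold lower (-4.41 ± 0.43, adjusted p = 0.00027, n = 3 per group) and Agrn, which encodes agrin, 20.1-fold lower (-4.33 ± 0.59, and -3.38 without treated aly replicate 1). Il15ra, the chain that presents interleukin 15, was 15.3-fold lower (-3.94 ± 0.53, -3.16 without that array, and -1.88 on its other probe set) and Il15 itself 9.51-fold lower (-3.25 ± 0.35). Stat4 (-3.66 ± 0.40, 12.7-fold), the antiviral Mx1 (-3.48 ± 0.49, 11.1-fold), Cxcl11 (-3.45 ± 0.39, 11-fold, other probe set -0.54) and Prnp, the prion protein gene (-3.35 ± 0.39, 10.2-fold), were lower as well. So were Cd80 (-3.28 ± 0.39, 9.7-fold, adjusted p = 0.00051, other probe sets -0.54, -1.41 and -0.55), the inhibitory ligand Cd274 (-3.16 ± 0.37, 8.94-fold) and the guidance receptor Gpr183 (-3.06 ± 0.42, 8.37-fold, other probe set -1.43). Fas (-3.03 ± 0.39, 8.16-fold), the transcription factor Irf4 (-2.72 ± 0.33, 6.59-fold, other probe set -0.12) and Il6 (-2.67 ± 0.39, 6.38-fold) completed this group, each of which was called without any 1 of the 12 arrays. Ccr7 (-1.83 ± 0.38, 3.57-fold, adjusted p = 0.014), Relb (-1.92 ± 0.44, 3.79-fold, adjusted p = 0.021) and Cd86 (-1.66 ± 0.39, 3.16-fold, adjusted p = 0.024) were also lower. Nfkb2 (-1.06 ± 0.48, adjusted p = 0.2) and Il12b (-0.21 ± 0.40, adjusted p = 0.79) were not called. Cd40 was not called either (-0.88 ± 0.50, adjusted p = 0.31), but was lower without treated aly replicate 1 (-1.61, adjusted p = 0.012).

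On the other side, Slc4a1 (4.02 ± 0.71, 16.2-fold, adjusted p = 0.0058, other probe sets 0.37 and 4.96) and the haem-degrading enzyme gene Hmox1 (3.99 ± 0.77, 15.9-fold, adjusted p = 0.0097) were higher in treated aly DCs. The macrophage gene Aif1 (3.74 ± 0.59, 13.3-fold, adjusted p = 0.0039, and 3.09 without treated aly replicate 1) and the haemoglobin scavenger receptor Cd163 (3.72 ± 0.68, 13.2-fold, adjusted p = 0.007) were higher as well. Cd163 averaged 4.23 in treated WT, under the added 16, and 355 in treated aly, so its fold depends on the 16. Of the 75 genes higher in untreated aly DCs, 41 were also higher in treated ones (2.05 expected if the calls were independent). Of the 8 lower ones 1 was also lower (0.211 expected, Fisher exact p = 0.19). The comparisons share no arrays, but their calls share 1 spread per gene, which by itself favours overlap. Without treated aly replicate 1 these overlaps were 128 of 288 higher genes (11.9 expected) and 11 of 108 lower genes (3.22 expected). Called genes numbered 807, 411 higher and 396 lower, and 1068 without treated aly replicate 1 (620 and 448), with 650 in common.

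Interferon-stimulated genes were lower in 21 of 32 cases (26 adjusted over the list alone), among them Gbp2 (6.25-fold, other probe set at a log2 difference of -0.53), Cmpk2 (5.04-fold, other probe set -0.01) and Parp14 (4.61-fold, other probe set -0.32). Their median was -1.78 (-2.05 in replicates 2 and 3, -1.38 in replicate 1, adjusted p = 7.1e-22, and 0.047 with an estimated correlation). Maturation genes were lower in 9 of 22 cases (12 lower and 1 higher adjusted over the list alone). Their median was -1.33 (-1.47 in replicates 2 and 3, -0.59 in replicate 1, adjusted p = 6.3e-11, and 0.013 with an estimated correlation). Negative feedback genes were lower in 6 of 17 cases (10 adjusted over the list alone, median -1.45, adjusted p = 1.6e-08, and 0.033 with an estimated correlation), with Socs1 4.27-fold lower, to a level of 12.9 under the added 16. The NF-kB pathway was lower with 3 of 21 members called (6 adjusted over the list alone, median -0.86, adjusted p = 1.9e-07, and 0.065 with an estimated correlation). These were Relb, Rel (3.86-fold) and Tnfaip3 (3.25-fold). MHC class I genes were lower with 1 of 15 called, Nlrc5 at 3.12-fold (3 lower and 1 higher adjusted over the list alone, median -0.51, adjusted p = 0.0042, and 0.092 with an estimated correlation). Red pulp macrophage genes were higher in 7 of 12 cases (10 adjusted over the list alone), and in 5 without treated aly replicate 1. Their median was 2.99 (3.85 in replicates 2 and 3, 1.53 in replicate 1, adjusted p = 1e-06, and 0.23 with an estimated correlation). Of 7 erythroid genes 2 were higher (5 adjusted over the list alone, median 1.17, adjusted p = 0.0031, and 0.16 with an estimated correlation).

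The count in treated DCs was 499 and 81 without WT treated replicates 1 and 3, 303 and 1544 without aly treated replicates 2 and 3, 231 with an offset of 1, 507 with median centring (16.6% higher, against 50.9% as deposited), 1184 with the spike-in batch as a block and 746 in replicates 2 and 3 alone. Fitting only the groups compared gave 27, and array weights gave 2886. The 3' over 5' covariate without treated aly replicate 1 gave 2. Calls were lost for Slc4a1, Hmox1, Cd163 and Rel without WT treated replicate 3 (adjusted p = 0.06, 0.087, 0.055 and 0.06), for Relb, Ccr7 and Tnfaip3 without it or aly treated replicate 2 (up to 0.13, 0.1 and 0.089), and for Cd86 and Nlrc5 without either or WT treated replicate 1 (up to 0.15 and 0.17).

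**Figure D5:**
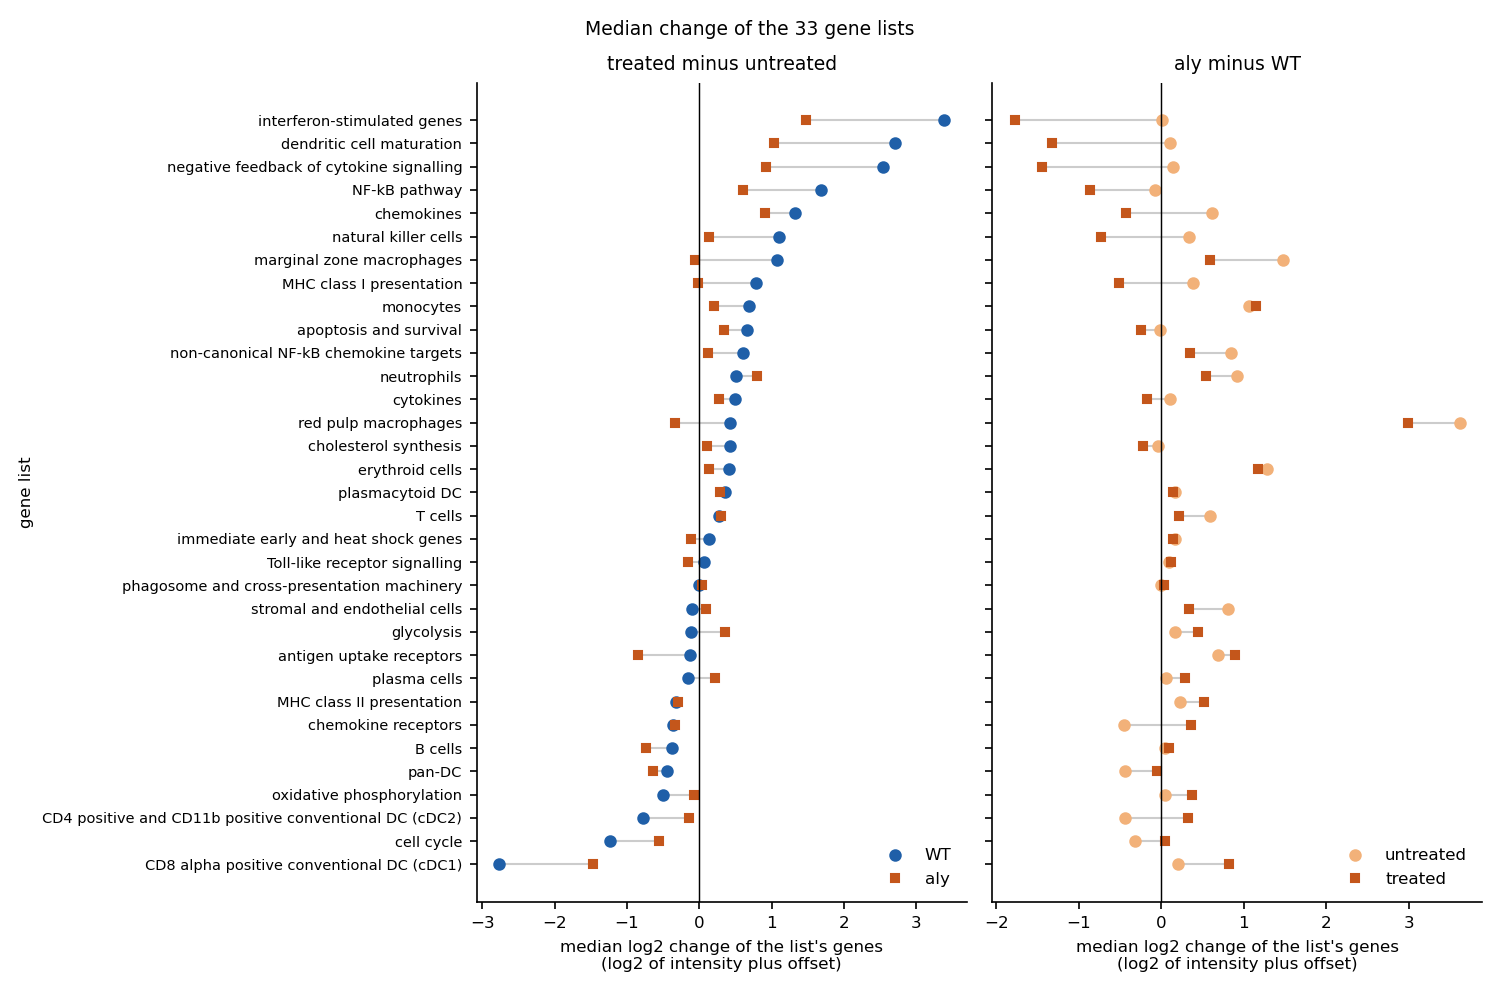
Median log2 change (horizontal axis) of the measured genes of each of 33 lists (vertical axis), for treated minus untreated in WT (circles) and aly (squares) at the left and for aly minus WT in untreated (circles) and treated (squares) DCs at the right. Interferon-stimulated genes stood at 3.39 for treatment in WT, 1.48 for treatment in aly and -1.78 for genotype after treatment.

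The response itself differed for Prnp, which had the largest difference (-5.00 ± 0.55, adjusted p = 0.0017, n = 3 per group). Prnp went from 344 ± 130 to 4860 ± 1090 in WT and from 1100 ± 349 to 466 ± 131 in aly, and was called without any 1 of the 12 arrays. Ccl22 responded less in aly (-4.34 ± 0.64, adjusted p = 0.011), with levels of 87.8 and 5800 in WT and of 773 and 1990 in aly. Smaller responses were also called for Gbp2 (-3.96 ± 0.55, adjusted p = 0.01, other probe set -1.54), the secreted protease gene Htra1 (-3.92 ± 0.57, adjusted p = 0.011), the myosin gene Myh10 (-3.83 ± 0.55, adjusted p = 0.011, other probe set -0.05) and Il15 (-3.61 ± 0.50, adjusted p = 0.01). Cd80 (-2.96 ± 0.55, adjusted p = 0.046, other probe sets -0.10, -1.04 and -0.50), Fas (-2.96 ± 0.56, adjusted p = 0.046) and Il2ra (-3.23 ± 0.56, adjusted p = 0.036, other probe set -1.52) passed narrowly. Untreated WT levels of Htra1, Myh10, Fas and Il2ra averaged 3.40, 8.57, 12.7 and 3.67, so the sizes of these differences depend on the added 16. In total 23 genes were called, all with a negative difference, that is less rise or more fall in aly than in WT. Without treated aly replicate 1 there were 113, with 96 negative and 17 positive differences. Over all genes 1204 interaction tests had an unadjusted p under 0.05.

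The responses of Relb (-1.64 ± 0.62, adjusted p = 0.5), Nfkb2 (-1.56 ± 0.68, 0.6), Cd86 (-1.80 ± 0.55, 0.35), Ccr7 (-1.30 ± 0.54, 0.57) and Il12b (-0.31 ± 0.56, 0.93) were not called different. That of Cd40 (-1.47 ± 0.71, adjusted p = 0.64) was called only without treated aly replicate 1 (-2.20, adjusted p = 0.04). Of the largest WT rises, Sphk1 (-3.32, adjusted p = 0.051), Il1rn (-2.95, 0.066), Plk2 (-3.63, 0.093), Ramp3 (-3.01, 0.24), Oasl1 (-2.58, 0.34) and Ifng (-2.83, 0.53) did not pass. Neither did the WT falls Adgrl3 (2.45, adjusted p = 0.067), Gpr34 (2.55, 0.31), Xcr1 (2.19, 0.63) and Rab7b (2.04, 0.71). Without treated aly replicate 1 Sphk1, Il1rn, Plk2, Oasl1 and Adgrl3 passed (adjusted p = 0.017, 0.035, 0.011, 0.032 and 0.021), and the differences of Oasl1, Ifng and Rab7b became -3.22, -3.78 and 2.85.

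As a list, interferon-stimulated genes responded less in aly, with 1 of 32 called over all genes and 19 adjusted over the list alone. Their median was -1.76 (-1.85 in replicates 2 and 3, -2.02 in replicate 1, adjusted p = 1.1e-23, and 0.028 with an estimated correlation). Maturation genes responded less with 2 of 22 called and 10 adjusted over the list alone. Their median was -1.51 (-1.49 in replicates 2 and 3, -0.69 in replicate 1, adjusted p = 9.6e-12, and 0.01 with an estimated correlation). Negative feedback genes did so with 0 of 17 called by limma (7 adjusted over the list alone, median -1.43, adjusted p = 2.3e-08, and 0.024 with an estimated correlation). MHC class I genes did so with 0 of 15 called by limma (1 adjusted over the list alone, median -0.96, adjusted p = 1.6e-05, and 0.024 with an estimated correlation, which became 0.076 without treated aly replicate 1). The NF-kB pathway also responded less, with 0 of 21 called by limma (0 adjusted over the list alone, median -1.11, adjusted p = 8.4e-06, and 0.1 with an estimated correlation).

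The interaction count was 8, 1 and 9 without WT untreated replicates 1 to 3, 7, 9 and 7 without aly untreated replicates 1 to 3, 7, 12 and 5 without WT treated replicates 1 to 3, 10 without aly treated replicate 2, 1 with an offset of 1, 55 with an offset of 64, 9 with quantile normalization, 8 with median centring, 31 with the spike-in batch as a block and 5 in replicates 2 and 3 alone. Calls were lost for Gbp2, Htra1, Myh10 and Il15 without WT untreated replicate 2 (each adjusted p = 0.053), for Ccl22 without it or WT treated replicate 3 (up to 0.053), and for Cd80, Fas and Il2ra without 11, 11 and 10 of the arrays (up to 0.22, 0.22 and 0.2).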

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

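The results below were picked out because the response to treatment differed between the genotypes. The tests on macrophage and erythroid RNA, on the low-quality array, on the 3' over 5' ratio of the WT arrays and on the 10 fallen cDC1 members were chosen after the result was seen, and those with the 3' over 5' ratio as a covariate used a setting added after the data were seen.

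In the interaction 23 genes passed the threshold. Of those named, the log2 difference in response was -5.00 for Prnp, -4.34 for Ccl22, -4.06 for Vsig10, -4.01 for Il15ra, -3.96 for Gbp2 and -3.92 for both Htra1 and Prdm1. It was -3.89 for the adhesion gene Pvr, -3.83 for Myh10, -3.82 for Pla1a, -3.61 for Il15, -3.53 for Cxcl11, -3.23 for Il2ra, and -2.96 for both Cd80 and Fas. Without treated aly replicate 1 the values were -3.23 for Il15ra and -3.20 for Prdm1. Other probe sets read -1.54 for Gbp2, -1.68 for Il15ra, -1.52 for Il2ra, -0.05 for Myh10, -0.68 for Cxcl11, -0.10, -1.04 and -0.50 for Cd80, and -2.79, -1.96, -2.21, 0.16 and -0.17 for Pvr.

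Of the lists, interferon-stimulated genes (camera adjusted p = 1.1e-23), DC maturation (9.6e-12), negative feedback of cytokine signalling (2.3e-08), MHC class I presentation (1.6e-05) and the NF-kB pathway (8.4e-06) responded less in aly. With an estimated correlation the NF-kB pathway did not pass (adjusted p = 0.1), and MHC class I presentation passed (0.024) but not without treated aly replicate 1 (0.076). Chemokines (0.00015, and 0.26 with an estimated correlation), apoptosis and survival genes (0.037, and 0.13), cytokines (0.038, and 0.39), natural killer cell genes (0.038, and 0.46) and non-canonical NF-kB chemokine targets (0.047, and 0.4) did so as well. Cell cycle genes (adjusted p = 0.0089, median 0.47) and cDC1 markers (adjusted p = 0.03, median 0.82) fell less in aly, with adjusted p of 0.49 and 0.59 with an estimated correlation.

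Maturation and interferon-stimulated genes rose less in aly than in WT. If dilution of DC RNA by RNA of other cells were the whole cause, increments and pan-DC levels would keep the same share. The 46 of 54 members that rose in WT kept a median share of 0.206 of their WT increment in aly (95% bootstrap interval 0.173 to 0.307). Without treated aly replicate 1 the share was 0.158 (0.125 to 0.179). The levels of 12 pan-DC genes in untreated aly over untreated WT had a ratio of 0.741 (0.507 to 0.986). These intervals resample genes and carry none of the spread between arrays. The 46 members were kept because they rose in WT, which by itself lowers their share in aly. The pan-DC ratio gives the share of DC RNA only if the other cells lack these genes, which was not tested. The interval of the increment share lay under that of the ratio, but for these reasons this does not decide on dilution. The low-quality array is unlikely to be the cause. Without treated aly replicate 1 the median interaction was -1.80 against -1.69 with it, and 53 of 54 members lay below 0. With the 3' over 5' ratio as a covariate the median was -1.78. With that covariate and without the array it was -1.74, and the fry test passed in both. These values do not decide on loss of 5' sequence, since the mean log2 ratio was at least 2.1689 on aly arrays and at most 1.8343 on WT arrays. A covariate added to the group means cannot model a response dampened on all aly arrays. What stays open is whether the weaker response reflects the loss of NIK signalling in the DCs themselves or a different mix of DC subsets. Dilution, a weaker signal from other cells of aly mice, and loss of 5' sequence on the aly arrays also stay open. These arrays do not separate them.

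Macrophage and erythroid genes were higher in untreated aly, list calls that were both lost with an estimated correlation (adjusted p = 0.12). RNA from red pulp macrophages and erythroid cells left after the bead and flow sort is a candidate explanation that no test singles out, since the differences of the 19 genes before and after treatment correlated at r = 0.79 over arrays that the contrasts do not share, which a stable genotype difference within the DCs or loss of 5' sequence would also give. The gene C1qa read 3440 ± 1500 in untreated and 3630 ± 1640 in treated aly (243 ± 342 and 563 ± 544 in WT). Loss of 5' sequence may contribute and was not separated, since with the 3' over 5' ratio as a covariate the macrophage median was 3.69 and passed the fry test, but was 2.01 and did not pass without treated aly replicate 1, the array that sets the range of the covariate. The erythroid median was 1.28 in the main fit, 0.95 with the covariate and 0.96 with it and without that array. Whether other cells were carried over, or DCs of aly mice themselves express more of these genes, stays open.

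Markers of cDC1 fell in treated WT, a list call that was lost with an estimated correlation (adjusted p = 0.23). Of the 16 members, the 95% intervals of 6 (Cd24a, Snx22, Irf8, Id2, Batf3 and Ly75) lay wholly above the list median of -2.77. This does not decide on a smaller share of CD8 alpha positive cells. A smaller share lowers a marker in full only if the other sorted cells do not express it, which was not tested. A smaller share alone would not raise Ly75, a listed marker of these cells, which rose by 2.17. Loss of 5' sequence is unlikely, since the mean log2 3' over 5' ratio differed by -0.016 between treated and untreated WT arrays. For the 10 members that fell, 0 intervals left out the list median, so a smaller share of these cells and a shared regulation of these genes may both hold for them.

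Other groupings of the 6 arrays of a contrast are too few to reach a share under 0.05. The real grouping was 1 of 10 splits in each case, with 1458, 73, 83 and 807 calls for treatment in WT, treatment in aly, genotype untreated and genotype treated, against at most 0, 0, 0 and 100 in the other splits. The split with 100 calls joined WT treated replicates 1 and 3 with aly treated replicate 1. For the interaction, 4 of 100 draws of genotypes within treatments, the real one included, gave at least 23 calls. The highest other draw gave 93, several times the real count. It kept the 3 treated WT arrays together as 1 genotype and mixed only the untreated arrays. The genotype difference after treatment thus entered its count. Such draws are no clean null for the interaction where the genotypes differ. The 4 of 100 therefore do not decide whether chance could give the 23 calls.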

How the results depend on the processing

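Of the results on named genes under all alternatives, 19104 kept their side of the threshold, 699 passed newly and 1299 no longer passed, with 0 reversed. For lists these were 1496, 52 and 101, and 1 reversed, the neutrophil list in treated aly, whose estimate changed sign in replicates 2 and 3 only, where it was not called (adjusted p = 0.98). For genes and lists, a change of sign counted as reversed only if the result was called in the main fit or under the alternative. The kept results thus include sign changes of results called in neither. All 5 counts moved by over 1.5 times under some alternative, and for each the cause was not tested unless stated. With 1 array left out, the counts ran from 587 to 2843 (treatment in WT), 13 to 102 (treatment in aly), 0 to 396 (genotype untreated), 81 to 1544 (genotype treated) and 1 to 113 (interaction). The smallest log2 sizes called were 1.07, 1.63, 1.57, 1.18 and 2.57 in the same order. In simulated arrays a log2 change of 1 in WT was called for 1.5% of genes at the spread of the real arrays and for 22.4% with all arrays alike, while signal over background was not tested as a limit.

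Counts are given in that order of contrasts. Offset 1 gave 898, 11, 0, 231 and 1 by limma, and offset 64 gave 51 for genotype untreated and 55 for the interaction. Median centring gave 893, 45, 0, 507 and 8, and quantile normalization 9 for the interaction. No filter gave 39 for genotype untreated and 12 for the interaction. All probe sets singly gave 2237 for treatment in WT, 127 and 1297 for the genotypes, counting probe sets. Array weights gave 3370, 164, 617, 2886 and 360. Fits of only the groups compared, from fewer samples, gave 2895, 6, 393 and 27. They were not run for the interaction, which uses all groups. The counts rose in the contrasts without treated aly arrays and fell in those with them. The main fit takes 1 spread per gene from all 12 arrays, treated aly replicate 1 (array weight 0.13) included. There, contrasts with treated aly borrow spread from tighter groups, and the others carry spread of that array. Settings added after the data were seen gave 120 and 176 (spike-in block, treatment in aly and genotype untreated), 28, 231 and 5 (replicates 2 and 3 only, also the interaction), 3139, 30, 235, 1243 and 64 (without the 2 arrays of highest Actb ratio), 2928, 520 and 70 (spike-in block without treated aly replicate 1, treatment in WT, genotype untreated and interaction), 2781, 41, 133 and 103 (3' over 5' covariate, all but genotype treated) and 2889, 0, 2 and 108 (that covariate without treated aly replicate 1, all but treatment in aly).

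Called lists numbered 14, 15, 11, 7 and 12. They were 7, 3, 0, 3 and 4 with the estimated correlation, and 5, 5, 11 and 6 by fry from treatment in aly onward. Without treated aly replicate 1 they were 9 (treatment in aly) and 14 (genotype treated), in replicates 2 and 3 only 8 and 12, and without the 2 arrays of highest Actb ratio 5 (genotype untreated) and 15 (genotype treated).

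The replicate number as a block gave 1666, 91, 133, 1108 and 30 calls. The labels do not say that a number marks a pairing, and correlations of deviations were -0.031 to 0.303 for the 18 same-number pairs (median 0.092, 8 over 0.1) and -0.295 to 0.227 for the 36 others (median -0.07). The other probe set of Map3k14 read a log2 difference of 0.402 in untreated DCs against 0.076.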

Other observations

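The tests in this part were set before their results were seen, apart from the genes said to be chosen later.

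Natural killer cell genes rose in treated WT DCs, 4 of 11 over all genes and 5 adjusted over the list alone (median 1.10, adjusted p = 9.5e-05, and 0.11 with an estimated correlation), and 1 of 11 in treated aly DCs (2 adjusted over the list alone, median 0.13, adjusted p = 0.013, and 0.33 with an estimated correlation). The risen members Gzmb (4.28 ± 0.56, 19.4-fold, from a level of 2.80 under the added 16), Gzma (10.6-fold), Tbx21 and Ccl5 encode granzymes, a transcription factor of type 1 responses and a chemokine that activated DCs also express. Whether these rises, and that of Ifng, came from DCs or from natural killer cells left after the sort was not tested. Gzma lost its call without WT untreated replicate 2 or 3 or WT treated replicate 1 (adjusted p up to 0.1), and Tbx21 without replicate 1 or 3 of either WT group (up to 0.078). Plasmacytoid DC genes rose in WT with 4 of 14 called and 1 lower (5 and 1 adjusted over the list alone, median 0.36, adjusted p = 0.0086, and 0.2 with an estimated correlation). Spib (8.18-fold) and Bst2 (6.31-fold) rose and the homing receptor Ccr9 fell 6.08-fold (-2.61, other probe sets -1.56, 0.52 and -0.95), and Bst2 is itself interferon-induced. In aly their median was 0.29 (adjusted p = 0.033, 0.36 with an estimated correlation and 0.16 without treated aly replicate 1), and after treatment Spib was 5.63-fold lower in aly than in WT.

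Of 15 chemokine receptors 4 rose and 4 fell in WT (4 and 6 adjusted over the list alone, median -0.37, adjusted p = 0.82). Ccr7, the B cell zone receptor Cxcr5 (10.6-fold) and Gpr183 (4.93-fold) rose, and Xcr1 and the T cell associated Cxcr3 (11.5-fold) fell. In untreated aly DCs the list was lower (0 of 15 called by limma, 1 higher and 2 lower adjusted over the list alone, median -0.45, adjusted p = 0.0049, and 0.41 with an estimated correlation). After treatment its median was 0.36, its mean -0.26 and the test pointed down (adjusted p = 0.22). MHC class II genes moved both ways in WT, with 2 rising and 6 falling among 18 (3 and 6 adjusted over the list alone, median -0.32, adjusted p = 0.46, and adjusted p = 0.038 for a fall by fry). The protease gene Lgmn (8.1-fold) and the maturation marker Cd83 (3.29-fold) rose, and the peptide exchange gene H2-DMa (4.8-fold) and the ubiquitin ligase gene Marchf1 (4.55-fold) fell. In untreated aly DCs 3 members were higher (4 adjusted over the list alone, median 0.23, adjusted p = 0.31), the lysosomal protease genes Ctsd, Lgmn and Ctsl (2.47, other probe set 0.82), which macrophages also express, and the sign of the median turned with the scaling.

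Among 20 antigen uptake receptors in WT, 2 rose and 4 fell (6 and 7 adjusted over the list alone, median -0.13, adjusted p = 0.82), with the lectin Cd209a down 8.2-fold. In aly this list fell with treatment (0 called by limma, 1 up and 4 down adjusted over the list alone, median -0.85, adjusted p = 0.018, 0.44 with an estimated correlation and 0.19 without treated aly replicate 1). Phagosome genes did not move as a list in WT (2 of 25 up and 1 down, 2 and 2 adjusted over the list alone, adjusted p = 0.77), although Rab34 rose 4.54-fold. Toll-like receptor signalling genes did not either (4 of 21 up and 2 down, 5 and 2 adjusted over the list alone, median 0.07, adjusted p = 0.29). Cholesterol synthesis genes rose in WT (3 of 16, 3 adjusted over the list alone, median 0.42, adjusted p = 0.011, and 0.064 with an estimated correlation), with the kinase gene Pmvk up 4.41-fold.

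Glycolysis genes had a median of -0.12, a mean of 0.22 and an upward test in WT (2 of 14 called up, 3 up and 2 down adjusted over the list alone, adjusted p = 0.33). The phosphofructokinase activator gene Pfkfb3 rose 7.95-fold. In aly the list rose (0 called by limma and 0 adjusted over the list alone, median 0.35, adjusted p = 0.032, and 0.33 with an estimated correlation). Oxidative phosphorylation genes were not called in WT (0 of 22 by limma, 0 adjusted over the list alone, median -0.50, adjusted p = 0.1), while fry gave adjusted p = 0.0024 for a fall. Immediate early and heat shock genes had a median of 0.13 and a mean of -0.22 in WT (2 of 18 up and 3 down, 2 and 3 adjusted over the list alone, adjusted p = 0.93). Among them Jun rose 4.31-fold and Egr3 fell 11-fold (-3.46, other probe set -0.53).

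Of the other cell markers in WT, cDC2 genes (1 of 13 up and 1 down, 1 and 3 adjusted over the list alone, median -0.78, adjusted p = 0.32), B cell genes (3 of 15 down, 4 adjusted over the list alone, median -0.38, adjusted p = 0.1) and T cell genes (1 of 11 up, Il7r at 10.2-fold, 3 up and 1 down adjusted over the list alone, median 0.27, adjusted p = 0.17) were not called as lists. Plasma cell genes had a median of -0.16 and a mean of 0.55 (2 of 9 up, 2 adjusted over the list alone, adjusted p = 0.24), with Prdm1, also a regulator of activated DCs, up 8.28-fold. Neutrophil genes (1 of 11 up and 1 down, 2 and 1 adjusted over the list alone, median 0.51, adjusted p = 0.074) included Lcn2, an antibacterial gene that LPS induces in many cells, up 23.2-fold from a level of 5.50 under the added 16. Stromal and endothelial genes (0 of 11 by limma, 0 adjusted over the list alone, median -0.10, mean 0.03, adjusted p = 0.75) were not called. In treated aly cDC1 markers fell (0 of 16 by limma, 2 up and 6 down adjusted over the list alone, median -1.47, adjusted p = 0.0017, 0.39 with an estimated correlation and 0.064 without treated aly replicate 1), and so did cell cycle genes (0 of 24 by limma, 0 adjusted over the list alone, median -0.56, adjusted p = 0.0047, 0.44 with an estimated correlation and 0.44 without that array). The neutrophil list rose there (0 called by limma, 0 adjusted over the list alone, median 0.80, adjusted p = 0.023, and 0.45 with an estimated correlation), but its median was -0.21 in replicates 2 and 3 and 3.68 in replicate 1. B cell genes fell there (0 called by limma, 0 adjusted over the list alone, median -0.74, adjusted p = 0.031, 0.45 with an estimated correlation and 0.16 without treated aly replicate 1). In untreated aly DCs cDC2 genes were lower (0 of 13 by limma, 1 higher adjusted over the list alone, median -0.44, adjusted p = 0.046, 0.45 with an estimated correlation and 0.074 without treated aly replicate 1).

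Some genes responded in aly with an interval of the difference in response that included 0. This was so for 1700011B04Rik (-0.60, 95% interval -1.75 to 0.55), Cnn3 (-0.80, -2.38 to 0.78), Saa3 (0.84, -1.66 to 3.34), Mt2 (0.19, -2.04 to 2.42), Aldh1a2 (-1.31, -3.20 to 0.58) and Sdc4 (-0.91, -2.82 to 0.99). Without treated aly replicate 1 the differences were -0.81, -1.32, -0.06, -1.0, -0.33 and -1.51, so those of Saa3 and Mt2 changed sign. The interval also included 0 for Gng4 (-1.97, -4.21 to 0.26), Hepacam2 (1.49, -0.07 to 3.04), Lpcat2 (-1.23, -2.54 to 0.08), Ramp1 (-0.22, -1.74 to 1.29) and Homer2 (-0.70, -2.24 to 0.84), at -2.99, 1.68, -0.94, 0.14 and -0.60 without that array. In aly the other probe sets of Gng4 read -0.06 and -0.43 against 3.61. An interval that includes 0 does not show an equal response.

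Flanking DNA that differs between the genotypes could change genes near Map3k14. Of the 100 measured genes nearest to it, 4 (4%) were called in either genotype contrast, against 844 of 14918 others (5.7%), with a one-sided Fisher exact p of 0.82, so no such excess was found. The 4 were Slc25a39, Slc4a1, Vat1 and Stat5a, of which Slc25a39 and Stat5a were chosen after their values were seen. The lack of an excess does not exclude such an effect on a single gene. The order of genes came from assembly GRCm38.p6.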
